A study of Mus musculus with 2 samples.

How the data were processed

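Total RNA of the size range above 200 bases was measured by sequencing in 2 libraries of 100 MEP cells each, with spike-in RNAs, per the labels. Per the README beside the tables, the authors quantified genes and transcripts against the mm10 assembly and GENCODE annotation M4. The aligner and quantifier versions are not given in the sources used here; the deposited column names are those that RSEM writes. The deposited expected counts are estimated reads or fragments per gene or transcript, which need not be whole. The deposited TPM values were scaled by the authors for effective length and to a fixed sum over all features, so abundant ribosomal RNA lowers the TPM of every other gene. The authors also deposited FPKM values, which were not used for results. The percent of a gene's TPM in each transcript was computed by the authors. The deposited score columns, posterior standard deviations of counts, and the deposited signal columns, bounds of credibility intervals, were not used for results.

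The tables held 69691 features, of which 43346 were annotated genes, 26248 tRNA gene features and 96 spike-ins, and 129984 transcripts. Gene names, biotypes and coordinates came from GENCODE M21 on GRCm38, the assembly also called mm10, by gene identifier without version; 42462 genes matched and 884 did not. Both samples belonged to 1 group by their cell type label, and replicate numbers came from the labels. The libraries were checked for duplication: a chi-square per degree of freedom of 62.8 over 11453 genes showed that they differed by far more than sampling noise. p-values were not computed, since 2 libraries of 1 group leave no comparison to test, and the spread between libraries may be technical.

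For each of 20 gene lists fixed before the data were examined, and for ribosomal protein genes, the median over members of the mean TPM was computed, with its percentile among 10000 random lists of protein-coding nuclear genes. The difference between libraries was log2(TPM + 1), replicate 2 minus replicate 1. It was set against 10000 random lists of protein-coding nuclear genes, matched on mean TPM in 20 bins. The pseudocount of 1 understates the change of low genes. Counting error was simulated from Poisson draws at each gene's mean TPM. Ratio intervals are exact Clopper-Pearson intervals at 95%, conditional on the total of the rounded expected counts. They, and the floor of 3 counts, cover counting error only, since reads are not independent molecules. A floor of 3 counts was 0.0598 TPM in replicate 1 and 0.0339 TPM in replicate 2 for a protein-coding gene of median effective length. TMM factors from edgeR 4.0.16 and size factors from DESeq2 1.42.0, in R 4.3.3 on rounded expected counts, were alternatives. Sequences were compared with blastn 2.17.0 at a word size of 11. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

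Genes were named by a rule fixed beforehand: the 4 highest members of each list, all members of the surface protein, globin and sex-linked lists, members of other-lineage lists at 10 TPM in both libraries, the 10 highest protein-coding nuclear genes, the 6 genes with the largest difference in each direction at a mean of 10 TPM and 50 counts, and isoform genes, of which the 6 highest and those whose main transcript differed. Some genes that the rule takes are not reported here. Alas2, Slc4a1, Gata1, Gata2 and Klf1 are list members outside that rule and were named after their values were seen. The 2 further lists used in the closing section were written before the values of their genes were seen, and the members named there were picked from them afterwards. On simulated data with 9982 genes, of which 200 changed, 5 of 5 lists of 20 genes changed by a log2 of 1 and 5 of 5 changed by a log2 of 2 were found in the comparison of replicate 2 with replicate 1, and 6 of 200 unchanged lists were. An SD of 0.5 put in came back as 0.484, taken over unchanged genes with high counts and with a pseudocount far under 1. The simulated genes varied independently and all had a mean of at least 1 TPM, so the check covers a simpler case than the data. The alternatives tried were other detection minimums, pseudocounts, filters, scalings, posterior means and each library alone.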

Results

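Total RNA was sequenced from megakaryocyte-erythroid progenitors (MEP), the bone marrow progenitors from which red cells and platelet-producing megakaryocytes arise, isolated as primary cells from male C57BL/6J mice of 5 to 6 weeks. There were 2 libraries, each made from 100 cells and labelled as biological replicates 1 and 2; the labels give them separate biosamples and the same donor record. The series had 1 group and no second condition, so the values describe MEP and the agreement of the 2 libraries, and no test between groups was possible. The gene tables summed to 30016974 expected counts in replicate 1 and 51510347 in replicate 2, of which 13518448 and 25799923 fell on protein-coding nuclear genes. Levels are given as the authors' TPM, a length-corrected share of all transcripts, as the mean of both libraries ± SD for a gene; for a list, the median over its members is given in each library.

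MEP expressed the regulators and products of the erythroid program at high levels. All 12 members of the list of transcription factors shared by the megakaryocyte and erythroid lineages reached at least 10 TPM in both libraries, with a list median of 68.9 TPM in replicate 1 and 78.1 TPM in replicate 2. Among them, Lmo2 stood at 181 ± 30.4 TPM (SD, n = 2), Ldb1 at 181 ± 30.9 TPM (SD, n = 2), Gfi1b at 147 ± 12.9 TPM (SD, n = 2) and Myb, a factor of proliferating progenitors, at 198 ± 14.7 TPM (SD, n = 2). Gata1 exceeded Gata2 by 2.90 times in replicate 1 and 2.83 times in replicate 2. Of 24 erythroid genes, 22 reached at least 10 TPM in both libraries, and the list median was 72.9 TPM in replicate 1 and 78.9 TPM in replicate 2. Car1 (ENSMUSG00000027556.11, mm10 chromosome 3, 14766216 to 14808368), a carbonic anhydrase of erythroid cells, was at 2114 ± 244 TPM (SD, n = 2), and Car2 was at 1035 ± 184 TPM (SD, n = 2). The biliverdin reductase gene Blvrb was at 301 ± 5.06 TPM (SD, n = 2) and the erythroid membrane protein gene Ermap at 229 ± 12.9 TPM (SD, n = 2). The medians of both lists, over the members' mean TPM, lay above those of all 10000 random lists of protein-coding genes of the same size. Those random lists held many genes with little or no expression, with typical medians of 0.7 and 0.505 TPM. The housekeeping, DNA replication and G2 and mitosis lists also lay above all of theirs, so this comparison shows expression and nothing particular to the erythroid program.

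Genes of the later red cell were uneven. The heme synthesis list had a median of 40.2 TPM in replicate 1 and 46.6 TPM in replicate 2, and 11 of its 12 members reached 1 TPM in both libraries. Alad, which makes porphobilinogen, was at 139 ± 9.36 TPM (SD, n = 2). Cpox and Urod were at 106 ± 24.7 and 118 ± 36.0 TPM (SD, n = 2). The exception was Alas2, the erythroid enzyme of the first step, at 0.88 TPM in replicate 1 and 0.07 TPM, from 2 counts, in replicate 2. Slc4a1, the anion exchanger of the mature red cell, was the erythroid gene under 1 TPM in both libraries. Of 7 globin genes, the 4 adult ones were measured: Hba-a2 at 139 ± 41.2 TPM, Hba-a1 at 117 ± 1.34 TPM, Hbb-bt at 84.0 ± 19.2 TPM and Hbb-bs at 54.4 ± 8.0 TPM (SD, n = 2). The embryonic genes Hba-x, Hbb-bh1 and Hbb-y had 0 counts in both libraries. The paired adult genes are near-identical copies, so the split of reads within each pair is uncertain.

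As a list, megakaryocyte genes were far lower than erythroid genes. Of 25 members, 9 reached 1 TPM in both libraries and 12 were under 1 TPM in both, with a list median of 0.81 TPM in replicate 1 and 0.49 TPM in replicate 2; the median of the members' mean TPM, 1.06, was at the 65.1 percentile of random lists. The highest was the integrin gene Itga2b, which encodes CD41, at 12.98 ± 2.16 TPM (SD, n = 2), and Lat and Fli1 were at 7.57 ± 2.96 and 5.95 ± 2.51 TPM (SD, n = 2). The erythroid median was 89.9 times the megakaryocyte median in replicate 1 and 161 times it in replicate 2. It was 67.3 times with medians over the mean TPM and 15.4 times with members at 1 TPM or more in either library only. The size of this ratio thus depends on the library and on how the medians are taken. The lists were not matched for stage of maturation, so it also depends on which genes were listed. Klf1, an erythroid factor, exceeded Fli1, a megakaryocyte factor, by 10.4 times in replicate 1 and 22.4 times in replicate 2.

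**Figure D1:**
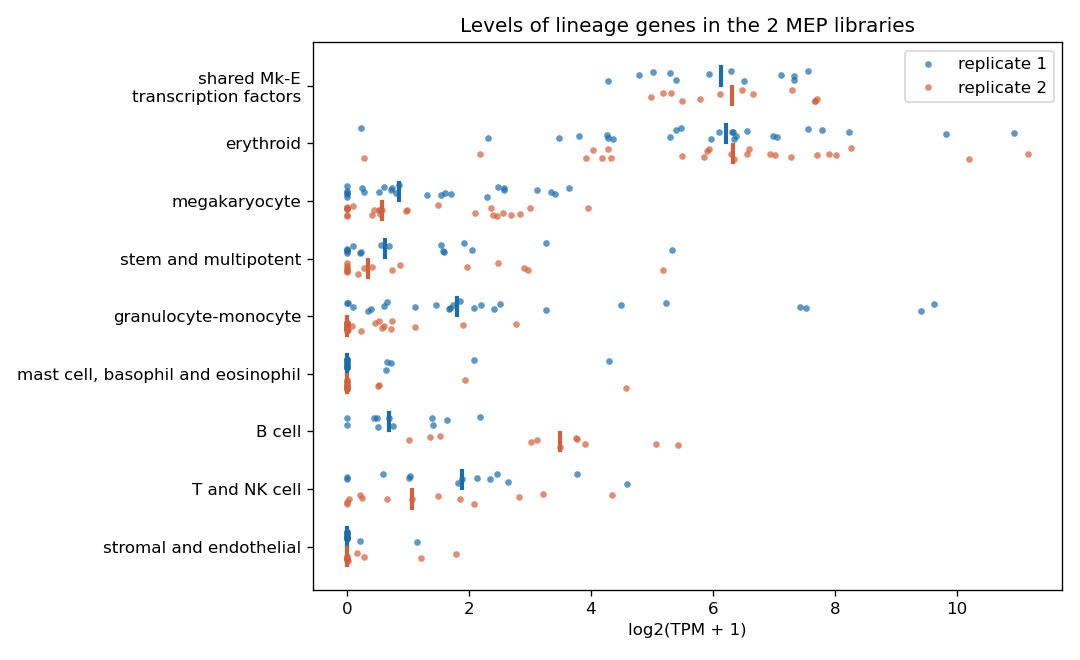
TPM of each member of the 9 cell type lists on a log2(TPM + 1) axis, for replicate 1 and replicate 2; each point is a gene and each vertical bar is the list's median in that library. The shared transcription factor and erythroid lists have medians of 68.9 and 72.9 TPM in replicate 1 and 78.1 and 78.9 TPM in replicate 2, and the granulocyte-monocyte, B cell and T and NK cell lists have median log2 differences of -1.28, 2.26 and -0.25 between the libraries.

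Genes of stem and multipotent cells were mostly low, with a median of 0.545 TPM in replicate 1 and 0.275 TPM in replicate 2, and 5 of 16 members at 1 TPM or more in both libraries. Mllt3 was the exception at 37.2 ± 2.96 TPM (SD, n = 2), and Meis1, Erg and Hoxa9 followed at 7.68 ± 1.26, 4.62 ± 2.59 and 3.86 ± 1.01 TPM (SD, n = 2). Among genes of surface proteins used to sort progenitors, Kit, the stem cell factor receptor, was at 86.5 ± 4.66 TPM (SD, n = 2), Eng at 43.6 ± 3.01 TPM (SD, n = 2) and Ptprc, which encodes CD45, at 40.1 ± 12.6 TPM (SD, n = 2). Cd34 was at 0.48 TPM in replicate 1 with 0 counts in replicate 2, Ly6a, which encodes Sca-1, was at 0.07 and 0.67 TPM, and Fcgr3 was at 2.63 and 0.68 TPM. Fcgr2b, Slamf1 and Il7r were at 2.33 ± 0.693, 2.47 ± 0.651 and 1.82 ± 1.10 TPM (SD, n = 2), and Cd3e was at 6.17 ± 2.93 TPM (SD, n = 2). Itgam was at 1.74 TPM in replicate 1 with 0 counts in replicate 2, Cd4 had 0 and 1 counts, and Cd8a and Ly6g had none. The list of surface proteins had medians of 1.79 and 2.71 TPM in replicates 1 and 2, and that of cytokine receptors 2.19 and 0.76 TPM. Of cytokine receptors, Epor, the erythropoietin receptor, was at 48.6 ± 14.6 TPM (SD, n = 2), Csf2ra at 7.36 ± 0.792 and Il6st at 1.76 ± 0.955 TPM (SD, n = 2).

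The cells carried a strong replication signature. All 15 genes of the DNA replication list and all 15 of the G2 and mitosis list reached 10 TPM in both libraries, with medians of 78.1 and 36.8 TPM in replicate 1 and 79.0 and 41.3 TPM in replicate 2. Pcna, the sliding clamp, was at 325 ± 37.8 TPM (SD, n = 2), the helicase subunit genes Mcm3, Mcm7 and Mcm6 at 205 ± 32.8, 156 ± 19.6 and 137 ± 2.75 TPM (SD, n = 2), and the proliferation marker Mki67 at 155 ± 31.1 TPM (SD, n = 2). Top2a, Ube2c and Aurkb were at 162 ± 12.2, 88.4 ± 3.92 and 53.0 ± 5.87 TPM (SD, n = 2). Immediate early and heat shock genes were low, with a list median of 3.26 TPM in replicate 1 and 3.12 TPM in replicate 2 and mean levels of Ier2, Dusp1, Hspa1b and Zfp36 between 7.36 and 11.1 TPM. The Y-linked genes Eif2s3y, Uty, Ddx3y and Kdm5d were at 49.4, 19.7, 12.9 and 10.5 TPM, and Xist had 0 counts in both libraries of these male animals.

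Genes of 2 other lineages separated the libraries. Granulocyte-monocyte genes were higher in replicate 1, where S100a8, a calcium-binding protein of neutrophils, was at 782 TPM against 5.81 TPM in replicate 2, a ratio of 135 (95% exact interval 102 to 181). S100a9 was at 677 against 0.52 TPM, a ratio of 1303 (95% exact interval 632 to 3242). Camp, a granule peptide gene, was at 170 against 0.06 TPM from 1 count, a ratio of 2837 (95% exact interval 509 to 112119). Ngp and Lcn2, further neutrophil granule genes, were at 182 and 40.9 TPM in replicate 1 with 0 counts in replicate 2, at least 2333-fold and 400-fold higher against a floor of 3 counts per library. B cell genes were higher in replicate 2. Vpreb1 (mm10 chromosome 16, 16868403 to 16870843), part of the surrogate light chain of early B cells, was at 32.5 TPM with 0 counts in replicate 1, at least 160-fold higher, and its neighbour Igll1 was at 41.8 against 0.43 TPM, a ratio of 97.1 (95% exact interval 47.0 to 242). Cd79a, a B cell receptor chain, was at 0.62 TPM in replicate 1 and 13.9 TPM in replicate 2, and the B-lineage factor Ebf1 was at 1.67 and 12.7 TPM.

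As lists, the median log2 difference, replicate 2 minus replicate 1, was -1.28 over 24 granulocyte-monocyte genes, with list medians of 2.49 and 0.005 TPM in replicates 1 and 2, below all 10000 random lists matched on mean TPM, and 2.26 over 11 B cell genes, with medians of 0.62 and 10.2 TPM, above all of them. The T and NK cell list, with medians of 2.71 and 1.10 TPM, had a median difference of -0.25, at the 0.99 percentile, and 7 of its 13 members reached 1 TPM in both libraries, Nkg7 being the highest at 21.1 ± 2.66 TPM (SD, n = 2). Its members went both ways: 3 of 13 exceeded the median log2 difference of 0.18 over genes with mean TPM of at least 1. Cd3g was at 12.6 TPM in replicate 1 and 1.10 TPM in replicate 2. Cd3e was at 4.1 and 8.24 TPM, a ratio of 2.01 (95% exact interval 1.63 to 2.49). Lck was at 5.25 and 6.06 TPM, a ratio of 1.15 (95% exact interval 0.982 to 1.36), which was not above that median difference. The other 6 of the 9 cell type lists lay within the central 95% of random lists. Their median differences were 0.32 for shared transcription factors, 0.22 for erythroid, -0.11 for megakaryocyte and 0 for the stem, mast cell and stromal lists. The megakaryocyte list was at the 4.06 percentile. Most members of the mast cell and stromal lists were under 1 TPM in both libraries. Their random range was 0 to 0, so the comparison could not show a difference for them. The mast cell, basophil and eosinophil list had a median of 0 TPM in both libraries, with Il1rl1 at 20.8 ± 3.01 TPM (SD, n = 2) and Cpa3 at 3.02 ± 0.276 TPM (SD, n = 2). The stromal and endothelial list also had a median of 0 TPM, with Pdgfrb highest at 1.84 ± 0.891 TPM (SD, n = 2). Of the 20 fixed lists compared this way, ribosomal protein genes included, 5 lay outside the central 95%. The other 2 were cytokine receptors, with a median difference of -0.17 at the 2.17 percentile, and abundant non-coding RNAs, with one of -0.16 at the 0.04 percentile. The random lists held protein-coding nuclear genes only, none with a mean TPM as high as that of Rn7sk. The non-coding list was thus matched neither on RNA class nor fully on level. With posterior mean TPM 3 lists lay outside, the T and NK cell and cytokine receptor lists being at the 3.53 and 3.49 percentiles. As CPM with TMM factors 6 did, with the shared transcription factors among them. The size of a list's median difference depended on the setting. Over the 5 alternatives it ran from -3.93 with a pseudocount of 0.1 to -1.13 with posterior means for granulocyte-monocyte genes. It was -2.51 over members with mean TPM of at least 1. It ran from 2.03 to 3.19 for B cell, from -0.45 to -0.23 for T and NK cell, from -0.71 to -0.16 for cytokine receptor and from -0.68 to -0.17 for abundant non-coding RNA genes. Ratio intervals cover counting error only, and with 1 library on each side these differences describe the libraries, not MEP as a population.

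**Figure D2:**
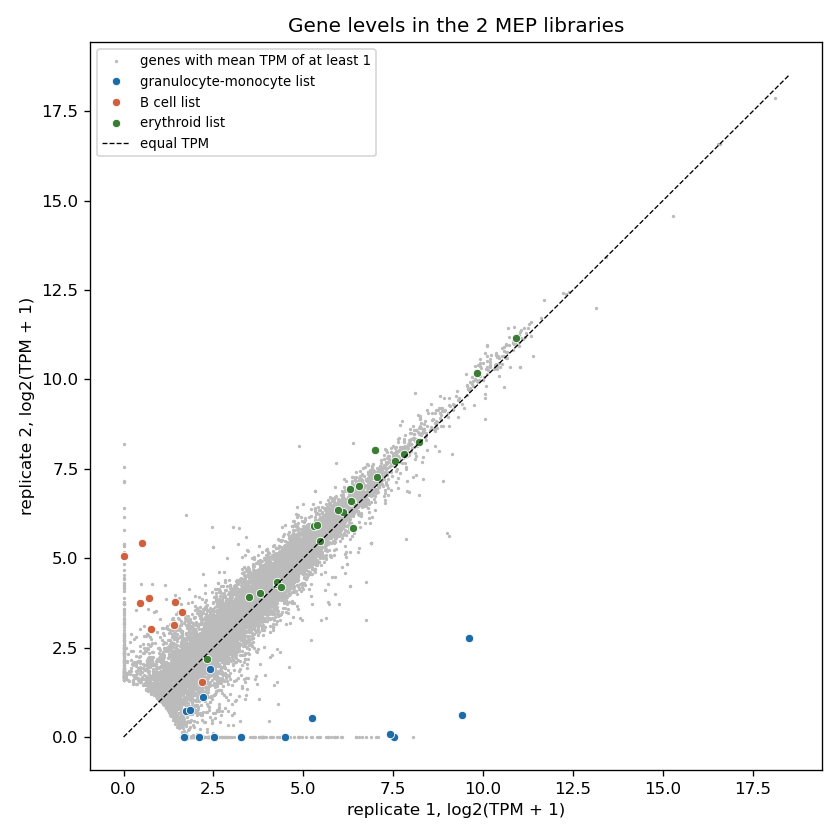
Level of each gene with mean TPM of at least 1 in replicate 1 (x axis) and replicate 2 (y axis), both as log2(TPM + 1), with the granulocyte-monocyte, B cell and erythroid lists in colour and a dashed line at equal TPM. The 11438 genes have a Spearman correlation of 0.914; erythroid genes lie near the line, granulocyte-monocyte genes below it and most B cell genes above it.

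At 1 TPM or more, 11247 genes were detected in replicate 1 and 11301 in replicate 2, and 10479 in both, of which 9484 were protein-coding. Over the 11438 genes with mean TPM of at least 1, Spearman's rho was 0.914 and Pearson's r of log2(TPM + 1) was 0.907, both across genes, which are not independent replicates. The log2 difference had a median of 0.18 and an SD of 0.80, so differences between libraries are read against that shift. With a pseudocount of 0.1 the SD was 1.30. As CPM with TMM factors, without length correction and over 11375 genes, the median was 0.01 and the SD 0.57. Among 4870 protein-coding genes with 100 to 1000 mean expected counts the SD was 0.61, against 0.09 expected from counting reads alone. At 10000 to 100000 mean counts it was 0.23 against 0.02.

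Ribosomal and other structural RNA filled much of both libraries. Gm42418 (mm10 chromosome 17, 39846958 to 39848788), annotated as a long intergenic non-coding RNA and overlapping the 18S ribosomal RNA pseudogene Rn18s-rs5, took 32.5% ± 3.84 of counts (SD, n = 2). The pair of mitochondrial ribosomal RNAs took 16.1% ± 0.0576 and protein-coding nuclear genes 47.6% ± 3.57 (SD, n = 2). Of small structural RNAs, Rn7sk stood at 32015 ± 11036 TPM, Rpph1 at 5097 ± 484 TPM, Rmrp at 2142 ± 770 TPM and Rn7s1 at 1702 ± 557 TPM (SD, n = 2). Lars2, the mitochondrial leucyl-tRNA synthetase, had the highest mean TPM of protein-coding nuclear genes. It was at 8970 TPM in replicate 1 but at 4116 TPM in replicate 2, where Eef1a1 at 5561 TPM and Rps12 at 5331 TPM were higher. The 83 ribosomal protein genes had medians of 1332 and 1543 TPM in replicates 1 and 2 and the 13 housekeeping genes 86.9 and 114 TPM, with Ppia at 1813 ± 304, Actb at 992 ± 137 and B2m at 653 ± 39.9 TPM (SD, n = 2). The translation factor gene Eef1a1 was at 5475 ± 122 TPM (SD, n = 2), and the top 10 by mean TPM also held the ribosomal protein genes Rps12, Rpl41, Rps2, Rps18, Rplp1, Rpl26 and Rpl32, at 2472 to 5193 TPM. Spike-in RNAs took 4141 counts in replicate 1 and 4162 in replicate 2, which is 7248 and 12375 counts of cellular RNA for each spike-in count. Over the 25 spike-ins with counts in either library the SD of the log2 difference was 0.86. Among 8 spike-ins with at least 50 counts in both libraries it was 0.51.

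The most abundant transcript of a gene was the same in both libraries for 4105 of 5567 genes with several annotated transcripts and at least 5 TPM, 73.7% (95% Wilson interval 72.6 to 74.9). The interval treats genes as independent and does not cover variation between libraries. Lmo2 kept its main transcript at 96.9% and 97.2% of the gene's TPM in replicates 1 and 2, and Gfi1b at 71.9% and 84.0%. Myb and Ikzf1 also kept theirs, at 55.0% and 63.0% and at 50.2% and 55.6%. The main transcript differed for Nfe2, Zfpm1 and Kit: the transcript leading in replicate 1 made up 67.7% of Nfe2 there and 9.41% in replicate 2, 60.03% and 32.0% of Zfpm1, and 51.2% and 35.5% of Kit. These shares are estimates from short reads.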

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

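Counts outside the measurements reported above were seen in 2 kinds of feature. The 26248 tRNA gene features together held 4 expected counts in replicate 1 and 12 in replicate 2, a very small part of each library. By the labels, these libraries were made from RNA above 200 bases. The 884 gene identifiers without a name in the reference held 39911 expected counts in replicate 1, which is 0.133% of the library, and 75108 in replicate 2, which is 0.146%. No explanation was tested for either.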

How the results depend on the processing

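The TPM scale rested on the ribosomal RNA in the total. Rescaled over protein-coding nuclear genes, the median over members of the mean TPM became 178 TPM for shared transcription factors, 167 for erythroid, 2.64 for megakaryocyte, 0.961 for stem, 3.83 for granulocyte-monocyte, 13.8 for B cell and 4.15 for T and NK cell genes, against 76.6, 71.7, 1.06, 0.43, 1.56, 6.16 and 1.82 over all features, since the divisor is smaller. With Lars2 also left out, an alternative chosen after seeing the data, they were 181, 169.7, 2.70, 0.972, 3.91, 14.0 and 4.2. As CPM, without length correction, they were 118, 106, 1.38 and 0.821 for the first 4 lists. Restricting lists to members with 1 TPM in either library gave 4.71 for megakaryocyte, 3.86 for stem, 11.9 for mast cell and 1.25 for stromal genes, by construction. Posterior mean TPM gave 0.77 for stem, 0.085 for mast cell and 0.435 for stromal genes; the cause was not tested. Each library alone gave 68.9 to 78.1 for shared transcription factors, 72.9 to 78.9 for erythroid, 0.49 to 0.81 for megakaryocyte, 0.005 to 2.49 for granulocyte-monocyte, 0.62 to 10.2 for B cell and 1.10 to 2.71 for T and NK cell genes. A mean of 2 values lies within 1 SD of each, so leaving out a library says nothing about the stability of single genes or shares. The SD of the log2 difference was 1.30 with a pseudocount of 0.1 and 0.84 with none, the latter over the 11121 genes above 0 in both libraries. It was 0.73 without a filter, 0.73 at 10 TPM, 0.57 as CPM with TMM factors, 0.57 with DESeq2 size factors and 0.58 for protein-coding genes, the last chosen after seeing the data. The TMM and DESeq2 values also lack the length correction of TPM. Spearman's rho, which a pseudocount does not change, was 0.944 over those 11121 genes, which leaves out genes absent from 1 library. It was 0.875 over 6156 genes at 10 TPM, 0.885 over 15760 genes with posterior means and 0.947 over 9982 protein-coding genes. As CPM with TMM factors and with DESeq2 size factors it was 0.963. The genes kept differ between these settings, and the cause of the other changes was not tested. The shared transcription factor list passed beyond the central 95% of random lists as CPM with TMM factors and with DESeq2 size factors, at a median difference of 0.18 in both. The T and NK cell list fell within it with posterior means, at -0.23; the cause was not tested. The cytokine receptor list also fell within it there. Too few members of the mast cell and stromal lists had a mean of 1 TPM for a difference. The granulocyte-monocyte and B cell lists kept their side under all 5 alternatives, though not their size, at -3.93 to -1.13 and 2.03 to 3.19. The SD of spike-ins was 0.86, or 1.94 with a pseudocount of 0.1 and 0.51 at 50 counts. Of the TPM sum, Gm42418 made up 26.1%, mitochondrial ribosomal RNA 19.4% and protein-coding nuclear genes 42.8%, as length enters. The main transcript was shared for 69.4% of genes at 1 TPM, 80.5% at 20 TPM and 94.9% where it led with 60%. Genes in both libraries numbered 12534 at 0.1 TPM, 7567 at 5 TPM and 14583 at 1 TPM by posterior means. For the other lists, classes and named genes, under alternatives that keep both libraries, 179 values stayed within the spread of the libraries or on their side, 57 moved and 1 list difference, of cytokine receptors, came within the range of random lists.
No paired analysis was possible because there is 1 group.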

Other observations

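Of the tests below, that of Lars2 was chosen after its level was seen, and the 2 further lists were written after the lineage pattern was seen and before the values of their own genes were. Altogether 9 explanations were tested.

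Further lineage genes followed the pattern of the fixed lists. Of 17 further neutrophil genes, 15 had counts and all 15 were higher in replicate 1, among them Chil3 at 19.5 TPM, Pglyrp1 at 18.6 TPM against 0.90 and Wfdc21 at 12.7 TPM, with 0 counts of Chil3 and Wfdc21 in replicate 2. Of 11 further B-lineage genes, 10 had counts and all 10 were higher in replicate 2, among them Dntt, the template-independent DNA polymerase of lymphoid progenitors, at 18.2 against 0.73 TPM, Vpreb3 at 16.8 against 2.51 TPM and Lef1, which T cells also express, at 14.3 against 3.00 TPM. No member of either list was in a fixed list.

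The genes that differed most between the libraries also included models whose counts are uncertain. Gm20390, a protein-coding model, had 69.7 TPM in replicate 2 and 0 counts in replicate 1. The processed pseudogene Gm15536 had 293 TPM from 57.9 counts in replicate 2, and Gm13577 had 50.4 TPM from 89.8 counts in replicate 1. Both pseudogenes had 0 counts in the other library. The small RNA genes Gm26387 and Rnu12 were at 142 and 73.0 TPM in replicate 2. Reads of pseudogenes, short genes and overlapping models can be divided differently in each library.

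The lineage difference was weighed in 5 tests. Gene by gene capture of rare RNA molecules needed 25 to 75% of the further members to lie in the expected direction, and 100% did, which argues against it. The further neutrophil list had a median log2 difference of -1.35 and the further B-lineage list one of 1.33, each beyond all random lists, consistent with cells of those lineages or their RNA in 1 library each; sorted cells and free RNA were not separated, and the gate used is not given in the sources used here. The tests written before any list was seen asked for both libraries. That of mature neutrophils set the median of S100a8, S100a9, Ngp, Camp and Ltf against that of Mpo, Elane, Prtn3 and Ctsg. Its bound was met, with a ratio of 53.2 in replicate 1. In replicate 2 the medians were 0.06 and 0 TPM, near the floor, so this rests on replicate 1. The ratio cannot tell mature neutrophils from immature cells of their lineage, and Ly6g had 0 counts in both libraries. Granulocyte-monocyte progenitors stay open: Mpo, Elane, Prtn3 and Ctsg had a median of 3.43 TPM in replicate 1 and 0 TPM in replicate 2, and the highest was 4.70 TPM, between the bounds set for that test.

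The spread between the libraries exceeded counting error. It was 6.50 times the counting SD at 100 to 1000 mean counts, and since separate libraries differ by more than counting noise in general, this decides nothing about the cause. Losses of molecules that act on spike-ins and cellular RNA alike stay open: spike-ins with 50 counts had an SD of 0.51, against a central 95% range of 0.256 to 0.912 in count-matched gene sets, a wide range from 8 spike-ins. A different makeup of lineages also stays open. Of 9 cell type lists, 3 lay outside the central 95% of random lists, 2 of them with posterior means and 4 lists as CPM with TMM factors. Those lists hold few of the 4870 genes at 100 to 1000 mean counts, so they cannot decide what spread most genes. There an SD taken from the median absolute deviation, which a few outlying genes hardly move, was 0.51 against 0.09 from counting.

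Lars2 (mm10 chromosome 9, 123366927 to 123462666) stood 845 times above the median of 16 other mitochondrial aminoacyl-tRNA synthetase genes in replicate 1 and 293 times in replicate 2. That ribosomal RNA reads were counted there was tested against Gm42418, Gm26917, mt-Rnr1 and mt-Rnr2: the shared stretch of 95% identity was 0 bases at a minimum of 30, and the longest match of any kind over 9 Lars2 transcripts was 29 bases, which argues against reads of those 4 models. The sequence of the 28S ribosomal RNA was not analysed here, so reads of that RNA remain untested.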
